A study of Homo sapiens with 8 samples.

How the data were processed

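The samples were HAP1 cells, a near-haploid human line derived from chronic myelogenous leukaemia. Per the labels' protocols, cells were transfected with 10 nM of a pool of small interfering RNAs against RBM26, against RBM27, against both, or with a non-targeting pool, and RNA was taken after 48 h. There were 8 libraries, 2 in each of 4 groups, called siNT (non-targeting), siRBM26, siRBM27 and siRBM26+27 (the double knockdown). Polyadenylated RNA was made into strand-specific paired-end libraries that were pooled before sequencing, per the labels' protocols. The labels do not say whether the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

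The authors deposited estimated counts per transcript for each library, and the submitters' processing notes name Trimmomatic 0.33, Salmon 0.14.1 and the hg38 genome. Per the file headers the same table holds TPM values and transcript and effective lengths in bases, as Salmon writes them. Shares of transcript classes were computed from the counts and from the deposited TPM values. The effective lengths were not analysed here beyond a mean per library. A second deposited table gives the authors' RPKM values, 1 per group, the log2 fold changes of each knockdown against siNT, and the p-values and false discovery rates that go with them, and the submitters' processing notes name edgeR with no version. How the authors filtered and normalised the counts for that table is not given in the sources used here. All 205870 transcripts had the identifier, gene identifier, gene name and length of GENCODE release 29, so coordinates and gene classes were taken from that annotation of GRCh38, counted from 1. No column of per-sample values lacked a sample.

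Transcript counts were summed per gene and rounded to whole numbers. Genes were filtered with filterByExpr, scaled with TMM factors and tested with the quasi-likelihood F test of edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. All 8 libraries entered 1 fit with a mean for each group, so that the groups shared an estimate of the spread. Contrasts were each knockdown against siNT, each pair of knockdowns, and the departure of the double knockdown from the sum of the single knockdowns on the log2 scale. Fold changes are given on the log2 scale with standard errors (SE), and levels as CPM (counts scaled to a common library total) with the standard deviation (SD) of 2 libraries. Salmon divides reads between transcripts that share sequence, so values of near-identical genes such as histones and ribosomal protein genes with processed copies are uncertain. The estimation step itself was not repeated here.

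There were 24 gene lists, fixed before the data were examined, together with the tests, the alternatives and the rule for named genes. The camera tests of gene classes and of lists between the single knockdowns, and the naming of list members for the departure from the sum, were not among these and were added later. Lists were tested with camera from limma 3.58.1, two-sided, on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the lists of each contrast. Named genes were RBM26 and RBM27, then the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, a mean of at least 5 CPM, both knockdown libraries beyond both control libraries (not asked for the departure from the sum) and a symbol that is not clone-based, and then up to 4 called members of each list with the smallest adjusted p. The list members were named in the double knockdown, and in the single knockdowns and the departure for lists that camera called there. Transcript usage in the double knockdown was tested with diffSpliceDGE of edgeR and Simes p-values on rounded transcript counts.

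Depth was 9669399 estimated counts in siRBM26 replicate 2 and 93392156 to 157854674 in the other 7 libraries. At least 10 counts were found for 14390 genes in that library and for 19166 to 20714 genes in the others. The steps were tested on simulated counts with the means, library sizes and dispersions of these data. For the double knockdown the step held 20001 genes. The gene test recovered 45 of 50 genes changed 2-fold, 21 of 50 changed 1.5-fold and 0 of 50 changed 1.2-fold, with 13 false calls. For the departure from the sum it recovered 30 of 50 genes changed 2-fold and 4 of 50 changed 1.5-fold, with 12 false calls. Only 200 genes were changed in each simulation, against 11820 called here in the double knockdown and 2132 for the departure. The adjusted threshold was therefore stricter in the simulation, and recovery in these data may differ. The camera step found the 1 list raised 1.4-fold and made no false call. Its simulated genes varied independently, while the lists used here had estimated correlations of up to 0.726. The simulation therefore does not show how the preset of 0.01 performs on them. The transcript usage step, run on 13360 genes, recovered 5 of 200 genes whose main transcript was lowered 4-fold and made 128 false calls, and it called 116 genes in data with no change. With dispersions set to 0.02 the same step recovered 195 of 200 genes with 29 false calls, so the wide dispersion of the transcript estimates (median 0.207) limits it.

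Alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter, a filter on a mean of 1 CPM, fits of only the groups compared, the replicate number as a block, leaving out each library, a minimum fold of 1.2 (glmTreat), protein-coding genes only, and for lists an estimated correlation and fry. XIST and genes of the Y chromosome are not reported, and not every gene that the rule names is given.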

Results

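RNA levels were measured by sequencing of polyadenylated RNA in HAP1 cells 48 h after transfection of small interfering RNAs against RBM26, RBM27 or both, with a non-targeting pool as control. RBM26 and RBM27 are related genes for RNA-binding proteins with zinc finger and RNA recognition motifs. The series addresses genetic interactions, and these 4 groups of 2 libraries ask what each gene's loss does and whether losing both differs from the sum. Libraries held 96348556 and 99574335 estimated counts in siNT, 93743721 and 9669399 in siRBM26, 103915332 and 157854674 in siRBM27, and 98048382 and 93392156 in siRBM26+27. The shallow siRBM26 replicate 2 also had 5.28% of its counts on transcripts annotated as retaining an intron, against 2.13% to 2.56% in the other 7 libraries. Its shares on processed transcripts (3.6% against 1.18% to 1.26%) and on transcripts annotated for nonsense-mediated decay (4.03% against 2.06% to 2.30%) were also higher, and its count-weighted effective length was 2742.7 bases against 3157.0 to 3429.1. Of all genes, 21411 passed the filter and were tested.

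Both target transcripts were lower wherever they were targeted. RBM26 (ENSG00000139746.15, chromosome 13, 79311824 to 79406477) stood at 99.9 ± 2.73 CPM (SD, n = 2) in siNT, 37.6 ± 6.02 CPM in siRBM26, 126 ± 20.4 CPM in siRBM27 and 27.8 ± 2.97 CPM in siRBM26+27. RBM27 (ENSG00000091009.7, chromosome 5, 146203600 to 146289132) stood at 94.2 ± 4.26 CPM in siNT, 97.4 ± 3.98 CPM in siRBM26, 15.1 ± 2.93 CPM in siRBM27 and 29.5 ± 1.54 CPM in siRBM26+27. On the log2 scale RBM26 changed by -1.43 (SE 0.145, adjusted p = 9.48e-05) in siRBM26 and by -1.84 (SE 0.142, adjusted p = 4.72e-06) in the double knockdown. RBM27 changed by -2.64 (SE 0.130, adjusted p = 5.22e-06) in siRBM27 and by -1.67 (SE 0.125, adjusted p = 3.89e-06) in the double knockdown. The remaining RBM27 transcript was higher in the double than in the single knockdown, by 0.97 (SE 0.125, adjusted p = 1.75e-04), so the 2 conditions were not matched in RBM27 level. The RBM26 difference between the double and the RBM26 knockdown, -0.41 (adjusted p = 0.0503), did not pass the threshold. Neither did RBM26 in siRBM27 (0.33, adjusted p = 0.103, but 0.0494 without siRBM27 replicate 2 and 0.00688 with no filter) or RBM27 in siRBM26 (0.04, adjusted p = 0.816).

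**Figure D1:**
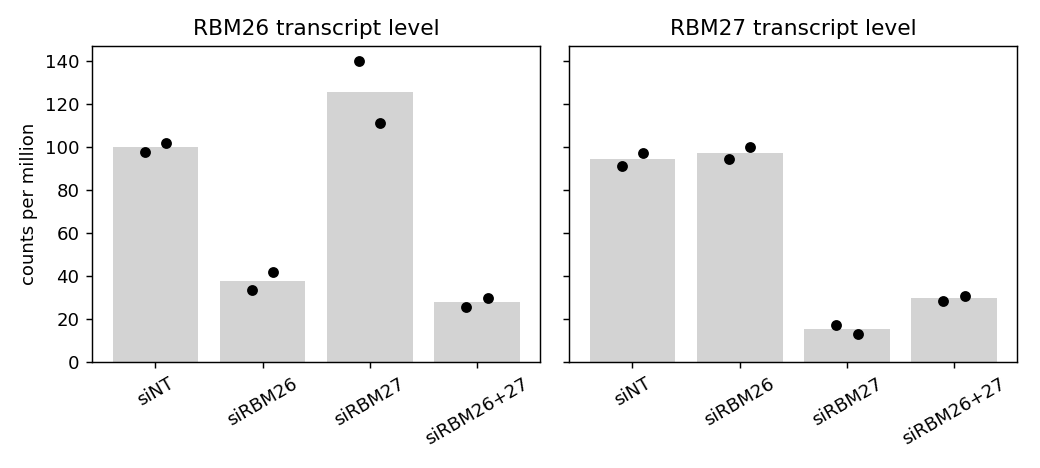
Levels of RBM26 (left) and RBM27 (right) in CPM for each library (points) and the mean of each group (bars), with the group on the horizontal axis. RBM27 averaged 15.1 CPM in siRBM27 and 29.5 CPM in siRBM26+27.

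After RBM26 knockdown, genes of cell division and of the stress response driven by the transcription factor ATF4 were lower, while the largest rises were those of HES5 and OLIG3. None of the list calls behind this held with an estimated correlation (adjusted p = 0.323 for mitosis, 0.182 for replication and 0.391 for ATF4 targets). HES5, a Notch target (ENSG00000197921.5, chromosome 1, 2528745 to 2530245), rose by 5.04 (SE 0.14), OLIG3 and NEUROG2, transcription factors of the nervous system, by 4.61 (SE 0.216) and 2.77 (SE 0.101), and CCND1, which encodes cyclin D1, by 3.17 (SE 0.114). Other large rises were CHI3L2 (4.04), OLFM3 (4.03), MEOX1 (3.06), the complement gene C3 (2.98), LBH (2.78) and OLFML3 (2.43). The largest falls included IL32, an inflammatory cytokine gene (-3.81, SE 0.451), the smooth muscle genes ACTA2 (-2.82, SE 0.275) and TAGLN (-2.81, SE 0.358), GLIPR1 (-2.84), CHAC1 (-2.80), IQGAP3 (-2.51), DRAM1 (-2.44), the NF-kappaB subunit gene RELB (-2.36), and the matrix genes COL7A1 (-2.35) and NID1 (-2.27). The adjusted p of these genes ran no higher than 3.35e-04. The siRBM26 libraries differed in IL32 (2.15 and 8.74 CPM) and TAGLN (16.7 and 46.0 CPM). Without siRBM26 replicate 1 IL32 stood at -2.71 and TAGLN at -2.21, and without siRBM26 replicate 2 they stood at -4.67 and -3.61.

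Mitotic genes fell in the RBM26 knockdown, with 28 of 30 measured members lower and 1 higher, and 29 lower adjusted over the list alone (median -1.40, camera adjusted p = 6.53e-15). CDC25C and CDC25B, phosphatases that start mitosis, changed by -1.86 and -1.63, and the checkpoint kinase gene BUB1 by -1.63. Genes of DNA replication fell in 27 of 30, with 27 adjusted over the list alone (median -0.89, camera adjusted p = 1.54e-12), among them CDC45, a part of the replicative helicase (-1.85), and RRM2, a ribonucleotide reductase subunit (-1.59). Among 29 ATF4 target genes 17 fell and 1 rose, with 20 lower adjusted over the list alone (median -0.55, camera adjusted p = 1.23e-06), including ASNS, asparagine synthetase (-1.82), and PHGDH of serine synthesis (-1.15). Interferon response genes fell in 16 of 33 and rose in 3, with the same counts adjusted over the list alone (median -0.39, camera adjusted p = 0.00189), and unfolded protein response genes fell in 10 of 20, with 11 lower and 1 higher adjusted over the list alone (median -0.28, camera adjusted p = 0.00834). IRF1, an interferon regulatory factor, changed by -1.05, and HSPA5, the main chaperone of the endoplasmic reticulum, by -0.52. Replication-dependent histone genes rose in 9 of 15, with 10 adjusted over the list alone (median 0.98, camera adjusted p = 5.75e-04), as HIST2H2BE did (1.77), and the median was 0.65 without siRBM26 replicate 1. Host genes of small nucleolar RNAs rose in 12 of 28 and fell in 2, with 13 and 2 adjusted over the list alone (median 0.56, camera adjusted p = 0.00834), and ribosomal protein genes rose in 10 of 36 and fell in 1, with the same counts adjusted over the list alone (median 0.25, camera adjusted p = 0.00385). Without siRBM26 replicate 1 these last 2 calls were lost, with medians of 0.35 and 0.12 and camera adjusted p = 0.0715 (0.00223 to 0.747 over all settings) and 0.0698 (0.00126 to 0.805). In siRBM26, mitochondrial genes took 2.59% and 3.64% of counts and the effective length was 3327.4 and 2742.7 bases, and whether this moved these lists was not tested. With an estimated correlation none of the 8 lists kept its call, with adjusted p from 0.182 to 0.805. In fry, which tests against no change, small nucleolar RNA hosts (adjusted p = 0.105) and ribosomal protein genes (0.16) lost it too.

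In all, edgeR called 6689 genes in the RBM26 knockdown, 2977 higher and 3712 lower, of which 1988 changed at least 2-fold. The count was 5899 without the shallow siRBM26 replicate 2, 3970 without siRBM26 replicate 1, and 3489 and 3590 without siNT replicate 1 and siNT replicate 2.

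**Figure D2:**
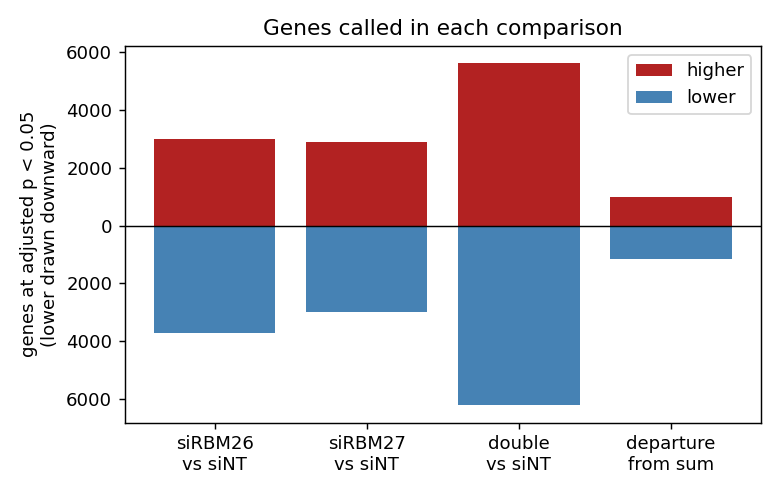
Number of genes at an adjusted p under 0.05 in edgeR, higher (upward bars) and lower (downward bars), for each knockdown against siNT and for the departure of the double knockdown from the sum of the single knockdowns. The double knockdown had 5609 genes higher and 6211 lower.

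After RBM27 knockdown, 21 of 30 replication genes, 11 of 30 mitotic genes and 18 of 29 ATF4 targets were higher, while 9 of 24 matrix genes and 10 of 18 fibroblast and epithelial markers were lower. None of these 5 list calls held with an estimated correlation (adjusted p = 0.172 to 0.378). TAGLN, which encodes transgelin, an actin-binding protein of smooth muscle, changed by -4.01 (SE 0.363), ACTA2, smooth muscle actin, by -2.85 (SE 0.256) and ANKRD1, a target of the coactivator YAP, by -3.64 (SE 0.186). Other large falls were GLIPR1 (-3.58), IL32 (-3.25), MEOX1 (-2.94), CTXN1 (-2.74), the muscle glycogen phosphorylase gene PYGM (-2.65) and the syndecan gene SDC4 (-2.43). The largest rises were the small nucleolar RNA host SNHG19 (3.22, SE 0.494, and 2.61 without siRBM27 replicate 2), DGAT2 of triglyceride synthesis (2.42, SE 0.112), the arginine synthesis gene ASS1 (2.28, SE 0.111), the angiopoietin gene ANGPT1 (2.03), SYT6 (1.95), SOX21 (1.92), the circadian clock gene PER2 (1.86), NAV3 (1.85), ADAMTS17 (1.79) and ST18 (1.75).

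Genes of DNA replication rose in 21 of 30, with 24 adjusted over the list alone (median 0.50, camera adjusted p = 4.19e-10), including the DNA repair gene UNG (1.41), MCM6 (0.92) and PCNA, the sliding clamp of replication (0.95). Mitotic genes rose in 11 of 30, with 13 adjusted over the list alone (median 0.29, camera adjusted p = 8.52e-05), as cyclin A2, CCNA2, did (1.16). ATF4 targets rose in 18 of 29 and fell in 1, with 19 and 1 adjusted over the list alone (median 0.39, camera adjusted p = 7.46e-06), including the amino acid transporter gene SLC7A5 (1.08) and PHGDH (0.94). Small nucleolar RNA hosts rose in 20 of 28, with 24 adjusted over the list alone (median 0.83, camera adjusted p = 5.28e-10), and ribosomal protein genes in 25 of 36, with 35 adjusted over the list alone (median 0.63, camera adjusted p = 1.14e-10), among them RPL30 (1.34). Histone genes rose in 5 of 15 and fell in 1, with 6 and 1 adjusted over the list alone (median 0.50, camera adjusted p = 0.0146), a call that was lost with a filter on a mean of 1 CPM (camera adjusted p = 0.0918, and 0.00658 to 0.344 over all settings). Cholesterol synthesis genes fell in 9 of 25, with 9 adjusted over the list alone (median -0.20, camera adjusted p = 0.00232). Matrix and adhesion genes fell in 9 of 24 and rose in 2, with 10 and 2 adjusted over the list alone (median -0.35, camera adjusted p = 0.00268), including SPARC (-1.91) and thrombospondin 1, THBS1 (-1.58). Fibroblast and epithelial markers fell in 10 of 18, with 11 adjusted over the list alone (median -0.64, camera adjusted p = 1.09e-04), the keratin gene KRT8 by 1.71 on the log2 scale among them. Oxidative phosphorylation genes rose in 4 of 30, with 4 adjusted over the list alone (median 0.23, camera adjusted p = 0.00672), and that call was lost without siRBM27 replicate 2 (camera adjusted p = 0.0623, and 3.54e-04 to 0.638 over all settings). The siRBM27 libraries had more counts on mitochondrial genes than siNT, 2.57% and 3.06% against 2.02% and 2.48%, and shorter count-weighted effective lengths, 3296.4 and 3208.0 against 3424.1 and 3429.1 bases, and whether this moved these lists was not tested. None of these 10 lists kept its call with an estimated correlation, where adjusted p ran from 0.172 to 0.638. Oxidative phosphorylation lost it in fry as well (adjusted p = 0.23).

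The RBM27 knockdown called 5862 genes in edgeR, 2884 higher and 2978 lower, of which 1434 changed at least 2-fold. The balance turned with DESeq2 size factors (2982 higher and 2904 lower), with no filter (3766 and 3006), with a mean of at least 1 CPM (2686 and 2543) and in DESeq2 (2819 and 2583). It also turned without siRBM26 replicate 1 (3116 and 3029), siRBM26+27 replicate 1 (2898 and 2669) or siRBM26+27 replicate 2 (2779 and 2626). Without siNT replicate 1 or siNT replicate 2 the count was 2498 or 2330.

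**Figure D3:**
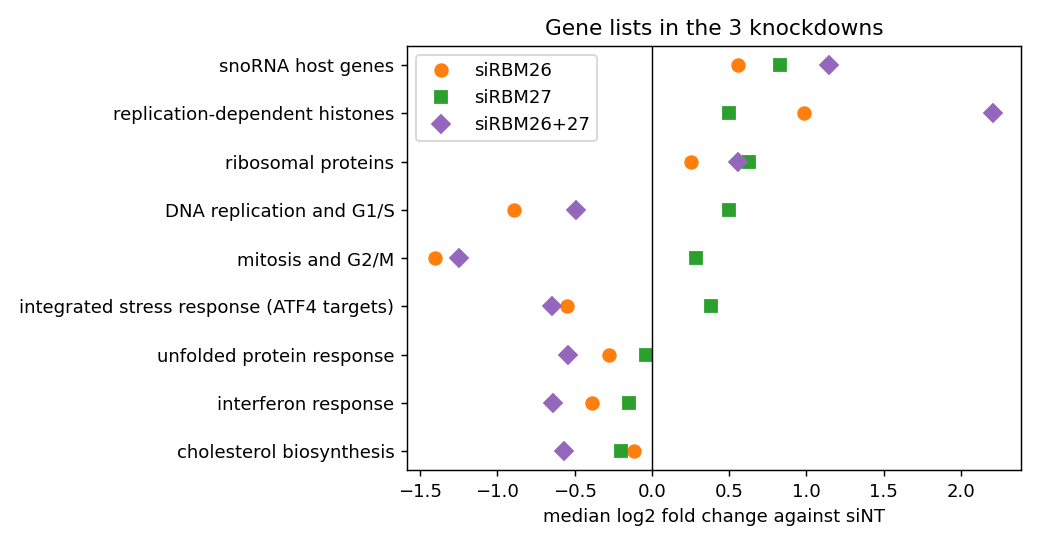
Median log2 fold change against siNT (horizontal axis) of the measured members of 9 gene lists (vertical axis) in siRBM26 (circles), siRBM27 (squares) and siRBM26+27 (diamonds). Medians of the DNA replication list were -0.89, 0.50 and -0.49 in that order.

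The single knockdowns were also compared directly. Genes of DNA replication were lower in siRBM26 than in siRBM27 in 28 of 30 measured members (median -1.44, camera adjusted p = 5.43e-16), mitotic genes in 29 of 30 (median -1.72, camera adjusted p = 6.22e-16) and ATF4 targets in 24 of 29, with 1 higher (median -0.999, camera adjusted p = 1.09e-09). Adjusted over the list alone the numbers lower were 28, 29 and 24. With an estimated correlation the adjusted p were 0.141, 0.223 and 0.223. The direct test called 8158 genes, 3828 higher and 4330 lower in siRBM26, with 7208 in all without siRBM26 replicate 2 and 5432 without siRBM26 replicate 1.

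Across genes, the log2 fold changes of the single knockdowns had a Pearson r of 0.308 (Spearman 0.263), where genes are not independent replicates. Counts simulated with no effect and the same shared controls gave a mean r of 0.42 over 20 data sets. The covariance was 0.198 against 0.082 in the simulation, and with a mean of at least 1 CPM it was 0.08 against 0.018. With each single knockdown set against its own siNT library, a setting chosen after the result was seen, r was 0.147 and 0.165 and the covariance 0.115 and 0.127 in the 2 ways of assigning the controls. There were 870 genes higher in both, against 401 for independent lists and 0.5 in the simulation, and 1013 lower in both, against 516.3 and 0.2. Almost no gene was called in the simulation, so its counts set no expected overlap for groups that changed. Another 787 genes were called in opposite directions, against 914.1 for independent lists. Part of the excess in the first counts may come from the shared controls, and the counts were not taken with separate ones. Without siRBM26 replicate 1 r was 0.142 and without siNT replicate 1 it was 0.464. TAGLN, ACTA2, GLIPR1 and IL32 were among the largest falls of both, while MEOX1 rose by 3.06 in siRBM26 and changed by -2.94 in siRBM27.

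With both genes knocked down, histone genes, hosts of small nucleolar RNAs and ribosomal protein genes were higher, and genes of division, ATF4 targets, unfolded protein response genes, interferon genes and cholesterol synthesis were lower. None of these 9 list calls held with an estimated correlation (adjusted p = 0.333 to 0.419). OLIG3 rose by 6.05 (SE 0.213), C3 by 5.80 (SE 0.198) and HES5 by 5.70 (SE 0.14), followed by OLFM3 (4.58), OLFML3 (4.39), CHI3L2 (4.25), SYT6 (4.02), the antisense transcript ZSCAN16-AS1 (3.97), LINC02487 (3.79) and CCND1 (3.6). IL32 changed by -6.86 (SE 0.496), TAGLN by -5.29 (SE 0.390), GLIPR1 by -4.77 (SE 0.249) and ACTA2 by -4.09 (SE 0.275). They were followed by annexin A1, ANXA1 (-4.06), the smooth muscle actin gene ACTG2 (-3.63), SAMD9 (-3.61), DRAM1 (-3.27), the creatine synthesis gene GATM (-3.15) and the centromere gene CENPK (-3.10).

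Histone genes rose in 13 of 15, with 13 adjusted over the list alone (median 2.20, camera adjusted p = 6.51e-06), including HIST1H2AC (2.85) and HIST2H2BE (2.35). These genes normally give transcripts without a poly(A) tail, and the RNA was selected for such tails. Small nucleolar RNA hosts rose in 23 of 28, with 23 adjusted over the list alone (median 1.14, camera adjusted p = 8.70e-07), among them SNHG3 (2.25), SNHG4 (1.94) and DANCR (1.47). Ribosomal protein genes rose in 29 of 36, with 29 adjusted over the list alone (median 0.56, camera adjusted p = 1.07e-06), RPL30 by 1.71 and RPL3 by 1.21. Mitotic genes fell in 28 of 30 and rose in 1, the same as adjusted over the list alone (median -1.25, camera adjusted p = 2.18e-09), including the kinase gene AURKB (-1.80). Replication genes fell in 24 and rose in 3 of 30, the same as adjusted over the list alone (median -0.49, camera adjusted p = 3.58e-05), including RFC3 (-2.21) and MCM3 (-1.56). ATF4 targets fell in 19 and rose in 1 of 29, the same as adjusted over the list alone (median -0.64, camera adjusted p = 3.13e-05), with ASNS at -2.31 and CHAC1 at -2.83. Unfolded protein response genes fell in 15 and rose in 2 of 20, with 16 and 2 adjusted over the list alone (median -0.54, camera adjusted p = 0.00288), including CALR, calreticulin (-0.88). Interferon genes fell in 19 and rose in 2 of 33, with 19 and 3 adjusted over the list alone (median -0.64, camera adjusted p = 0.00140), including DDX60 (-3.08) and IFIT3 (-2.11). Cholesterol synthesis genes fell in 18 of 25, with 18 adjusted over the list alone (median -0.57, camera adjusted p = 8.87e-05), including MVK, mevalonate kinase (-1.42), and LSS, lanosterol synthase (-1.40).

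The PAXT connection and nuclear exosome list, made of factors that target and degrade nuclear polyadenylated RNA, was not called (median 0.04, mean -0.04, camera direction down, adjusted p = 0.956, though fry gave 0.00248). Of its 24 members 6 rose and 7 fell, the same as adjusted over the list alone. Among all tested genes 55.2% were called in the double knockdown, so these members were near the general share. PABPN1, the nuclear poly(A)-binding protein gene, changed by -1.46 (SE 0.130, adjusted p = 1.12e-05), ZCCHC8 by -0.88 and EXOSC8 by -0.95. Among p53 targets 14 of 24 fell and 4 rose, with CDKN1A, the p21 gene, at -2.18 (SE 0.109), with 5 higher adjusted over the list alone, but the list missed the threshold (camera adjusted p = 0.0611). It passed without siNT replicate 1 (0.026), siNT replicate 2 (0.0395), siRBM26 replicate 1 (0.0492) or siRBM26+27 replicate 1 (0.0319), within 0.026 to 0.419 over all camera settings, and fry, which tests against no change, gave adjusted p = 7.16e-04. Markers of blood cells (5 rose and 5 fell of 12, camera adjusted p = 0.807, fry 0.00411) and of fibroblasts and epithelia (5 rose and 7 fell of 18, camera adjusted p = 0.807, fry 0.014) were not called by camera.

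Long noncoding genes rose as a class in the double knockdown, with 1569 of 4647 higher and 531 lower (median 0.51, camera adjusted p = 1e-05, and adjusted p = 0.0432 with an estimated correlation). Protein-coding genes had 3756 of 15376 higher and 5526 lower (median -0.10, camera adjusted p = 1.05e-05, and adjusted p = 0.00735 with an estimated correlation). The share of counts on long noncoding transcripts was 0.812% and 0.841% in siNT, 1.00% and 1.04% in siRBM26, 0.835% and 0.829% in siRBM27, and 1.19% and 1.26% in siRBM26+27, which was not tested. By TPM the share in siRBM26 replicate 2 was 1.59%, below the 1.76% and 1.83% of siNT. The double libraries also had more counts on mitochondrial genes, 3.35% and 4.46% against 2.02% and 2.48% in siNT, and shorter count-weighted effective lengths, 3157.0 and 3265.4 against 3424.1 and 3429.1 bases, which were not tested. The rise over protein-coding genes of the same mean CPM was 0.241, and the summed level of olfactory receptor genes was 18.2 and 21.1 CPM in the double knockdown against 14.3 and 14.2 CPM in siNT. The class was not called in siRBM26 (camera adjusted p = 0.154) or siRBM27 (camera adjusted p = 0.879).

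The double knockdown called 11820 genes in edgeR, 5609 higher and 6211 lower, of which 2855 rose and 2237 fell at least 2-fold. The balance turned to 5958 higher and 5851 lower with DESeq2 size factors and to 6739 and 5813 with no filter. Of all called genes, 4259 were called in neither single knockdown. Against the RBM26 knockdown 7204 genes differed, 3379 higher and 3825 lower, and against the RBM27 knockdown 10427, 4935 higher and 5492 lower. At least 2-fold, 1379 were higher and 778 lower against RBM26, and 2534 and 1390 against RBM27. Both balances turned with DESeq2 size factors (3696 higher and 3512 lower against RBM26, 5208 and 5178 against RBM27) and with no filter (4833 and 3257, 5579 and 5384), and the first also with a mean of at least 1 CPM (3272 and 2930), in a fit of only the libraries compared (3129 and 2768) and without siRBM26+27 replicate 2 (2339 and 2224). The count against RBM26 was 6275 without siRBM26 replicate 2, 4488 without siRBM26 replicate 1 and 4563 without siRBM26+27 replicate 2.

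Camera called departures from the sum of the single knockdowns for 9 lists, ATF4 targets, histones and YAP targets among them. Among all tested genes 10% were called for the departure. Splicing regulators, replication, mitotic, cholesterol synthesis and oxidative phosphorylation genes were called at or below that share. Their list calls thus rest on small shifts across members, not on an excess of called genes. ATF4 targets lay below the sum in 11 of 29, with 19 adjusted over the list alone (median -0.54, camera adjusted p = 4.43e-07), including ASNS (-1.37, SE 0.172) and STC2 (-1.03, SE 0.135). Histone genes lay above it in 5 of 15, with 6 adjusted over the list alone (median 0.65, camera adjusted p = 0.00587), including HIST1H2AC (1.25, SE 0.171). YAP and TGF-beta targets lay above it in 7 of 19, with 10 above and 1 below adjusted over the list alone (median 0.38, camera adjusted p = 0.00144), including CYR61 (1.24, SE 0.114) and the receptor kinase gene AXL (1.35, SE 0.168). With an estimated correlation each of these 3 had adjusted p = 0.404. Splicing regulators lay below the sum in 3 of 34 (median -0.21, camera adjusted p = 0.00284), replication genes in 3 of 30, with 4 adjusted over the list alone (median -0.20, camera adjusted p = 0.00634), mitotic genes in 2 of 30 (median -0.24, camera adjusted p = 0.0186) and cholesterol synthesis in 1 of 25 (median -0.20, camera adjusted p = 0.0258). Oxidative phosphorylation had 0 of 30 called (median -0.25, camera adjusted p = 0.0104), and fibroblast and epithelial markers lay above the sum in 3 of 18, with 5 adjusted over the list alone (median 0.40, camera adjusted p = 0.0382). Where no other count is given it was the same adjusted over the list alone. These 6 had adjusted p = 0.404 to 0.655 with an estimated correlation. All but mitosis lost the call without siRBM26 replicate 1 (adjusted p = 0.071 to 0.203), and mitosis lost it without siRBM26 replicate 2 (adjusted p = 0.208) or siRBM27 replicate 1 (0.0982). With a filter on a mean of 1 CPM the calls of replication (0.0624), mitosis (0.128), cholesterol synthesis (0.178) and oxidative phosphorylation (0.0572) were lost. In fry the calls of mitosis (adjusted p = 0.22), cholesterol synthesis (0.127) and oxidative phosphorylation (0.394) were lost. Cholesterol synthesis and oxidative phosphorylation lost it also without siRBM26+27 replicate 2 (0.245 and 0.449), oxidative phosphorylation without siRBM27 replicate 2 (0.051), and the fibroblast and epithelial markers without siNT replicate 1 (0.0758) or siRBM27 replicate 1 (0.081). Long noncoding genes lay above the sum in 283 of 4647 and below it in 46 (median 0.35, camera adjusted p = 6.02e-06, and adjusted p = 0.0403 with an estimated correlation). Single genes far above the sum were TCTE3 (2.70, SE 0.182), RND3 (2.52, SE 0.196) and C3 (2.23, SE 0.280), and far below it DDX60 (-2.38, SE 0.206), NUP62CL (-2.29, SE 0.188) and ZNF595 (-1.91, SE 0.171).

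In total 2132 genes departed from the sum, 980 above and 1152 below, and 795 by at least 2-fold, 575 of them above and 220 below. The excess below the sum was reversed with a mean of at least 1 CPM (1078 above and 849 below), with no filter (1745 and 1507), with DESeq2 size factors (1034 and 993) and against a 1.2-fold minimum (539 and 501). It was also reversed without siNT replicate 1 (271 and 249), siNT replicate 2 (170 and 163), siRBM26 replicate 1 (608 and 533) or siRBM26+27 replicate 2 (332 and 312). The double change lay beyond the sum, in its own direction, for 1365 of them and short of it for 298, with no expected split computed. Another 469 were not called in the double knockdown. The count was 333 and 520 without siNT replicate 2 and siNT replicate 1, 644 without siRBM26+27 replicate 2, 1141 without siRBM26 replicate 1, 1802 without siRBM26 replicate 2, 3252 with no filter and 1040 against a 1.2-fold minimum. RBM27 itself departed by 0.92 (SE 0.175, adjusted p = 0.0128), a call lost without siNT replicate 2 (adjusted p = 0.0715) or siRBM26+27 replicate 2 (0.0522). RBM27 was thus not at the level that the sum assumes.

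Transcript usage was tested in the double knockdown, and edgeR called 322 of 13368 genes. That count cannot be read as genes with changed usage, because the same step called 116 genes in simulated data with no change and recovered few of the changed genes planted in it. Leaving out 1 library gave 23 and 31 genes for the siNT libraries in order of replicate, 1222 and 1213 for siRBM26, 105 and 102 for siRBM27, and 80 and 43 for siRBM26+27. No gene is named from this test.

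In the authors' deposited table, 6913 genes had a false discovery rate under 0.05 for siRBM26, 6338 for siRBM27 and 11929 for the double knockdown, of 21254 genes, 21134 of which were also tested here. The authors' calls were 2790 higher and 4123 lower for siRBM26, 3423 and 2915 for siRBM27, and 6270 and 5659 for the double knockdown. For siRBM27 and the double knockdown that balance is the reverse of the one in the present edgeR fit. The genes called both in the authors' table and in the present fit numbered 6326, 5706 and 11199, and every one of them had the same sign in both. Both rest on the same libraries, so the shared sign is no independent check.

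**Figure D4:**
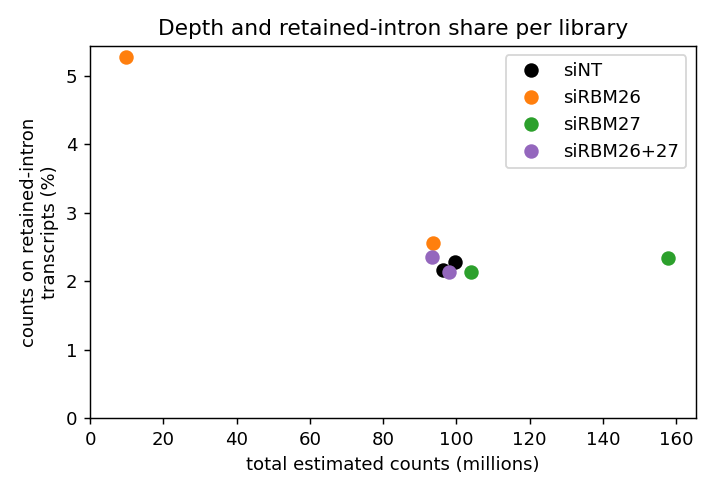
Total estimated counts per library (horizontal axis, in units of 1e6 counts) and percent of counts on retained-intron transcripts (vertical axis) for each of the 8 libraries, coloured by group. The library siRBM26 replicate 2 lies apart at 9669399 counts and 5.28%.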

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

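The tests of reads from the pool, of reads from the double knockdown libraries and of retained-intron shares were chosen only after the result was seen, and the tests of gene classes and of lists between the single knockdowns were not among those fixed in advance.

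The 2132 genes that departed from the sum were found by a test of the difference itself, as were the medians of 9 lists. Histone genes departed by 0.65, DNA replication genes by -0.20, mitotic genes by -0.24, ATF4 targets by -0.54, cholesterol synthesis by -0.20, oxidative phosphorylation by -0.25, splicing regulators by -0.21, YAP and TGF-beta targets by 0.38, and fibroblast and epithelial markers by 0.40. Long noncoding genes departed by 0.35 and protein-coding genes by -0.059 in the median. Several of these medians moved by over 1.5 times when 1 library was left out or the filter changed. With a mean of at least 1 CPM replication stood at -0.12, mitosis at -0.15, cholesterol synthesis at -0.13 and splicing regulators at -0.13. Without siRBM26 replicate 1 replication stood at -0.10, cholesterol synthesis at -0.10, oxidative phosphorylation at -0.09, the fibroblast and epithelial markers at 0.25 and histones at 1.02. Without siRBM26+27 replicate 2 replication stood at -0.12, cholesterol synthesis at -0.09 and oxidative phosphorylation at -0.07, and without siRBM26+27 replicate 1 replication stood at -0.30 and oxidative phosphorylation at -0.45. Mitosis stood at -0.11 without siRBM26 replicate 2 and -0.14 without siRBM27 replicate 1, and the fibroblast and epithelial markers at 0.61 without siRBM27 replicate 2. With an estimated correlation none of the 9 lists was called (adjusted p = 0.404 to 0.655).

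RBM27 was knocked down less in the double, and genes with a larger RBM27 effect departed more in the opposite direction. The slope was -0.255 (95% bootstrap interval over genes -0.285 to -0.225) when effect and departure came from separate control and siRBM27 libraries. Such intervals resample genes, which are not independent, and carry no spread between libraries. Responses that level off whichever gene is lost cannot be told apart from this weaker RBM27 knockdown. The slope on the RBM26 effect was 0.068 (0.035 to 0.1), past the bound set for excluding them. That bound took RBM26 to be as high in the double as in siRBM26. Its estimate was lower in the double (-0.41, edgeR adjusted p = 0.0503), though not past the threshold. A lower RBM26 would raise the slope, which was not tested, and this reading was adopted once the value was known. Among the called lists, histones (median 0.50 in siRBM27, 0.65 for the departure) and cholesterol synthesis (-0.20 and -0.20) departed in the direction of their siRBM27 change. The other called lists departed against it, as ATF4 targets did (0.39 and -0.54). The departure subtracts the siRBM27 change, so noise in those libraries also gives opposite signs. Part of the departure may come from the weaker RBM27 knockdown or from a levelling off. Neither was shown to account for the 1365 genes whose double change lay beyond the sum in its own direction, against 298 short of it. Both tests behind these counts use the double and siNT libraries, and no expected split was computed. The counts thus do not weigh against either explanation. An interaction of the genes remains an untested explanation, since the RBM27 level was not matched.

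Between the single knockdowns, the direct test gave medians of -1.44 for DNA replication, -1.72 for mitosis and -0.999 for ATF4 targets (siRBM26 minus siRBM27).

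Single genes above the sum were HIST1H4E (2.75), TCTE3 (2.70), RND3 (2.52), HIST1H3B (2.40), H2BFS (2.25), C3 (2.23), PURPL (1.94), MEOX1 (1.88), HIST2H2BD (1.83), ZSCAN16-AS1 (1.82), AHNAK2 (1.75), RBM47 (1.75), ACTA2 (1.58), COL3A1 (1.44), AXL (1.35), PDGFRA (1.33), HIST1H2AC (1.25), CYR61 (1.24), HIST1H2BD (1.202), BAMBI (0.95), SMAD6 (0.93) and RBM27 (0.92). Below the sum were DDX60 (-2.38), NUP62CL (-2.29), ZNF595 (-1.91), ZC3HAV1L (-1.83), GATM (-1.79), C11orf72 (-1.77), PHF6 (-1.77), SCML1 (-1.67), FAM122B (-1.63), TMOD2 (-1.63), ASNS (-1.37), RFC3 (-1.33), STC2 (-1.03), HNRNPA2B1 (-0.94), SLC7A11 (-0.92), PCK2 (-0.92), STARD4 (-0.90), HNRNPD (-0.84), MCM3 (-0.84), BUB3 (-0.82), RBM26 (-0.75), CCNA2 (-0.56) and HNRNPL (-0.56). Each of these passed the test of the departure, but many calls rest on single libraries. H2BFS kept its call without siRBM26 replicate 2 (3.07), lost it without any of the other 7 libraries (adjusted p = 0.0646 to 0.14) and in DESeq2 (0.257), and stood at 0.94 without siRBM26 replicate 1. RBM26 lost its call without any library but siRBM27 replicate 2 (0.0501 to 0.136), with DESeq2 size factors (0.0512) and with a filter on a mean of 1 CPM (0.0732). CCNA2 lost it without any library but those of siRBM27 (0.0607 to 0.134). Without siNT replicate 1 the calls of ACTA2, BAMBI, COL3A1, HIST1H4E, HNRNPD, HNRNPL, SMAD6 and STARD4 were lost (0.0521 to 0.123), and without siNT replicate 2 those of ACTA2, BAMBI, BUB3, C11orf72, COL3A1, HIST1H3B, HNRNPD, HNRNPL, MCM3, PCK2, RBM27, SLC7A11, SMAD6 and STARD4 (0.0512 to 0.11). Without siRBM26 replicate 1 HIST1H4E, HNRNPL, PCK2 and STARD4 were lost (0.062 to 0.104) and ACTA2 stood at 1.01. ACTA2 (0.0912) and COL3A1 (0.0583) were lost without siRBM27 replicate 1, ACTA2, COL3A1 and PCK2 without siRBM27 replicate 2 (0.0541 to 0.0674), COL3A1 without siRBM26+27 replicate 1 (0.0514), and ACTA2, HNRNPL, PCK2, RBM27, SLC7A11 and STARD4 without siRBM26+27 replicate 2 (0.0522 to 0.0942).

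In siRBM26 replicate 2, 5.28% of counts lay on retained-intron transcripts, above the 2.17% and 2.28% of the siNT libraries, and reads from the other libraries of the pool cannot raise that share, since the highest of them had 2.56%; the shares on processed (3.6%) and nonsense-mediated decay transcripts (4.03%) were raised too. For gene levels, fractions of reads from the pool fitted on genes lower and higher in siRBM26 replicate 1 differed by only 0.036 (0.205 and 0.169). That met the criterion set for mixing. In the siRBM27 and double pairs the same fit gave up to 0.189 on higher genes but only 0.017 to 0.095 on lower genes, below 0.205. Genes high in the double knockdown alone gave -0.194 (95% bootstrap interval over genes -0.355 to -0.087). Because the pool includes the double libraries, that value was counted against both, a reading adopted once both values were known; it rests on 14 genes, and their selection was revised after a first version gave -0.326 on 10 genes. Over 8629 abundant protein-coding genes, the thinned siNT pair spread only 0.462 times as widely as the siRBM26 pair. The thinned siRBM27 and double pairs reached 0.968 and 0.908 times its spread, but at full depth they already spread nearly as widely. Thinning widened the siRBM27 pair from 0.215 to only 0.226 and the double pair from 0.202 to 0.212, against 0.233 in the siRBM26 pair. This argues against counting noise as the cause for these abundant genes. Less abundant genes, where counting noise is larger, were not tested. A weaker response in replicate 2 or reads from only some libraries may also remain, and no biological explanation was tested, since both libraries are of the same group.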

How the results depend on the processing

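Only the setting with separate controls (Pearson r 0.147 and 0.165) was chosen after the result was seen. With 2 libraries per group, leaving out 1 leaves a lone library that is assumed to vary like the other groups. The 4 target gene changes kept their direction and side of the threshold in every setting run. Counts moved by over 1.5 times as follows. With no filter 3252 genes departed from the sum. Against a 1.2-fold minimum the counts were 4108 for RBM26, 3061 for RBM27, 1040 for the departure and 4476 for double against RBM26. With an estimated correlation 0 lists were called in each of the 4 contrasts, of 8, 10, 9 and 9, and fry, which compares a list with no other genes, called 19 in the double. Over the 4 contrasts fry gained 28 list calls, lost 6 and reversed 1. Among the gains was the PAXT and nuclear exosome list, which camera called in none of them. By fry it was lower in siRBM26 (adjusted p = 5.31e-04), the double (0.00248) and the departure (0.00644), and higher in siRBM27 (3.32e-04). Leaving out each library in turn gave 3489 to 7052 genes for RBM26, 2330 to 6219 for RBM27, 333 to 2086 for the departure, 4488 to 7502 for double against RBM26, 5432 to 7854 for RBM26 against RBM27, 4 to 12 lists for the departure, and a Pearson r of 0.142 to 0.464. For RBM26, RBM27 and the departure the lowest counts came without a siNT library. Over 8629 abundant protein-coding genes, the SD of log2 differences between replicates was 0.088 in siNT. It was 0.233 in siRBM26, 0.215 in siRBM27 and 0.202 in the double knockdown. The estimate of the spread that the groups share thus included a tighter pair, which is lost when a siNT library is left out. Whether this lowered the counts, apart from the fewer libraries, was not tested. Transcript usage gave 87 genes with a filter on 1 CPM, 674 with the gene-level F test and 23 to 1222 without each library. Fibroblast and epithelial markers in the double (median -0.25) were called higher by fry (adjusted p = 0.014), against this median and the uncalled downward direction of camera (0.807), and the cause was not tested. Of the settings of single named genes, 3702 kept side and direction, 82 lost the call, 2 gained it and 0 reversed; for lists these were 1135, 62, 50 and 1. The replicate block gave 7499, 6914, 12457 and 3035 genes for RBM26, RBM27, double and departure, against 6689, 5862, 11820 and 2132 without it. Deviations of same-numbered libraries correlated weakly between groups, by 0.019 to 0.183. These values do not decide whether the replicate numbers pair the samples. Depth limits low-abundance genes in siRBM26 replicate 2, where 14390 genes had at least 10 counts.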

Other observations

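No test of a technical explanation in this part was chosen after its result was seen, and the gene class test behind the pattern was not among those fixed in advance.

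In lists that were not called in the double knockdown, single members passed the gene test, as did 55.2% of all tested genes. PDGFRA and PDGFRB, receptors for platelet-derived growth factor, rose by 2.13 (SE 0.083) and 3.04 (SE 0.177), the receptor kinase gene KIT by 2.22 (SE 0.102) and the glucose transporter gene SLC2A1 by 2.17 (SE 0.089), while SLC2A3, another glucose transporter gene, changed by -1.26 (SE 0.120). TLR3, a sensor of double-stranded RNA, changed by -3.22 (SE 0.164) and BIRC3, an inhibitor of apoptosis, by -3.61 (SE 0.327). Among nuclear long noncoding RNAs FIRRE rose by 1.71 and TUG1 by 0.85, while MIAT changed by -2.11, and the list was not called (camera adjusted p = 0.451).

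The lists not called by camera in the double knockdown were glycolysis and hypoxia (camera adjusted p = 0.424), oxidative phosphorylation (0.845), splicing regulators (0.370), nonsense-mediated decay factors (0.956), heat shock (0.705), immediate early genes (0.780, median -0.13 and mean 0.19), YAP and TGF-beta targets (0.134), matrix and adhesion (0.235), apoptosis regulators (0.0968) and the RNA interference machinery (0.431). Oxidative phosphorylation passed without siRBM26+27 replicate 2 (0.0493) and apoptosis regulators without siRBM26+27 replicate 1 (0.0319). Against no change, fry called YAP and TGF-beta targets higher (adjusted p = 5.16e-04) and matrix and adhesion (5.16e-04), the RNA interference machinery (0.00248), apoptosis regulators (0.00678), splicing regulators (0.0227) and heat shock genes (0.0229) lower.

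The rise of long noncoding genes in the double knockdown was set against technical explanations. Intervals in this part resample genes, which are not independent, and carry no spread between libraries. Removing a transcript length trend fitted on protein-coding genes left a median of 0.521 (95% bootstrap interval 0.49 to 0.565), which argues against length as the cause. Low abundance stays open, because the excess over protein-coding genes of the same mean CPM was 0.241 (0.203 to 0.275). That is above 0 but just below the bound set for excluding it. Unmatched medians against siNT were 0.507 for long noncoding and -0.097 for protein-coding genes, so the excess was larger before matching. Genomic DNA also cannot be told apart, since summed olfactory receptor genes were 0.467 higher on the log2 scale, with 18.2 and 21.1 CPM in the double against 14.3 and 14.2 CPM in siNT, just under the bound set for it. Single-exon long noncoding genes rose more than multi-exon ones of the same mean CPM, by 0.258 (0.181 to 0.328). Without matching, their medians were 0.727 and 0.413. Protein-coding genes differed in the same direction, with unmatched medians of 0.432 for single-exon genes (0.36 without histone genes) and -0.106 for multi-exon genes. Genomic DNA or a slower decay of unspliced and short noncoding RNA may both give the difference among long noncoding genes. A change caused by the knockdown thus stays open beside the technical explanations, untested.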
